A study of Homo sapiens with 20 samples.

How the data were processed

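Gene expression was measured by sequencing total RNA, extracted with the Qiagen RNeasy midi kit per the labels' protocols. The RNA came from 5 cell lines, untreated or with torkinib for 72 h, 2 libraries per group. The deposited files hold counts of reads per gene symbol, whole numbers with no normalization, 1 file per library. Per the submitters' processing notes, HISAT2 2.04, HTSeq 0.6.1, limma 3.34.9 and the build hg19 (GRCh37) were used; their roles, the gene annotation and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart, and genes with near-identical copies, such as histones, ribosomal protein genes with pseudogenes, AMY2B, GTF2IRD2, AKR1C2 and KRT81, are uncertain, since reads that aligned at more than 1 place stood outside the genes. Of 50775 features 31339 had a count. Symbols were matched to a table of gene names and biotypes (GENCODE 29), which gave 27611 matches, 18757 of them protein coding; its coordinates belong to another build and were not used, so no positions are given.

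The summary lines of the counter, which name no gene, stayed out of library sizes and tests. Counted reads were 47.8 to 62.4% of all reads per library. Not aligned were 16.1 to 30.8%, aligned at more than 1 place 9.32 to 15.1%, in no feature 5.43 to 7.83%, of low alignment quality 2.96 to 5.36%, and ambiguous 1.08 to 1.57%. Counted reads per library, as replicates 1 and 2, were 6000784 and 6066431 in untreated 94T778 and 7529367 and 7510221 with torkinib. In the same order they were 6799559, 7481714, 5651045 and 4040023 in A375 and 5201967, 8756448, 9690786 and 7751066 in SKMEL28. They were 5982804, 7343664, 5535663 and 6773622 in SKBR3 and 9737903, 7521790, 5337649 and 7007764 in AU565. The 10 most counted genes took 4.39 to 12.1% of counts, and 17815 to 20455 genes had a count in a library. Replicates differed by more than sampling noise in each group, with a chi-square per gene of 1.37 to 3.37 and of 12.2 in untreated SKBR3. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicate numbers were not used to pair libraries.

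Counts were analysed in R 4.3.3 with edgeR 4.0.16, using the TMM factors, the filterByExpr filter (16698 genes tested) and 10 group means in 1 model, so that all groups shared the estimate of spread (common biological coefficient of variation 0.0547, prior degrees of freedom 25.6, residual degrees of freedom 10). Genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, for each line, for the average of the 5 lines, for any difference between lines and for the pairs A375 and SKMEL28, and SKBR3 and AU565. Changes are log2 fold changes, torkinib over untreated, with their standard error, and levels are normalised CPM (counts scaled to a common library size) as mean ± SD of 2 libraries. Levels given for single libraries, sums over marker lists, and the bounds and ratios for groups with few counts use CPM of library totals without those factors. Where a group had no counts, a fold is a bound against a floor of 3 counts over the group; with 1 to 3 counts a ratio is given with an exact 95% binomial interval. Such bounds and intervals cover counting error only. A fitted change against a group with no counts depends on the prior count, and 3525 of the 16698 genes had such a group, which leaves their average without a finite estimate. On the average edgeR called 399 of them and limma-voom 1348.

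Gene lists covered homologous recombination, Fanconi anemia, replicative and error-prone polymerases, 5 other groups of repair and checkpoint genes, replication, mitosis, G1, p53, FOXO, lipid and energy metabolism, ATF4, translation, degradation, stress and signalling, 4 lineages, the 12q amplicon, blood and endothelial cells, histones, mitochondrially encoded genes and MTOR complexes, 36 in all. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The list symbols MC1R and PECAM1 had no match. Each list was scored as the mean log2 CPM (prior count 2) and tested by a two-sided exact permutation of treatment within lines. Camera (limma 3.58.1) compared list members with other genes at a preset correlation of 0.01 and again with an estimated correlation; fry, a rotation test, asked whether a list moved on balance 1 way. Camera called 17 of 36 lists on the average, 13 lower and 4 higher, and 13 of the 17 kept the call with an estimated correlation; fry called 30.

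Named genes were chosen by rule: each polymerase with a value; the 6 homologous recombination and Fanconi anemia members with the smallest p; the 4 members with the smallest p of each other list; the 10 largest rises and falls among genes called the same way in all 5 lines; per line the 6 largest rises and falls called, at 8 CPM or more in the higher group and with torkinib libraries beyond both untreated ones; the 10 smallest interaction p among genes called in opposite directions; and the 5 largest differences each way in both pairs of lines. The last 4 parts left out clone-named loci, pseudogenes, small RNAs, XIST and Y-linked genes. MTOR was always given. Some genes that the rule took are not reported here.

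The model was tested on simulated counts with the real means, library sizes and a coefficient of variation of 0.055, in which 67, 67 and 66 of 16698 genes changed by 1.5, 2 and 4-fold. For the average it recovered 55.2, 77.6 and 83.3% of them. Recovery per line was 40.3, 68.7 and 84.8% in 94T778, 46.3, 67.2 and 84.8% in A375, 49.3, 71.6 and 84.8% in SKMEL28, 40.3, 62.7 and 72.7% in SKBR3, and 35.8, 68.7 and 81.8% in AU565, with 1.53 to 5.71% of calls false. A list shifted by -1 came back at -0.99, and none of 35 unshifted lists was called. Simulated genes were drawn independently, with 1 spread for all groups and few changed genes. The rates of false calls may therefore not carry over to lists of correlated genes or to untreated SKBR3, whose replicates differed most. Alternatives were DESeq2 (version 1.42.0), limma-voom, other scaling factors, filters and prior counts, a fold threshold, a replicate block, other list definitions, and leaving out each library or line in turn. Alternatives added after the data were seen left out the genes or libraries in doubt, or genes with no count in some group.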

Results

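RNA sequencing counts were collected from 5 established human cancer cell lines, untreated or treated for 72 h with torkinib (PP242). Torkinib is an ATP-competitive inhibitor of the MTOR kinase, which sits in 2 complexes that control growth and metabolism. No time is given for the untreated libraries. The lines were 94T778, from a well differentiated liposarcoma; A375 and SKMEL28, from melanomas; and AU565 and SKBR3, breast cancer lines with HER2 amplification that are known to come from the same donor. The dose was 10 µM in 94T778, 4 µM in A375, SKMEL28 and AU565, and 0.8 µM in SKBR3. Per the labels, doses were set to stop the cell cycle while cells stayed viable, so a difference in response between lines is also a difference in dose in every pair except those among A375, SKMEL28 and AU565. Each of the 10 groups held 2 libraries, 20 in all, with 4040023 to 9737903 counted reads per library. The smallest library was A375 torkinib replicate 2 and the largest AU565 untreated replicate 1. The series asks how MTOR inhibition changes the expression of genes for DNA repair, and the comparisons below are torkinib against untreated within each line, the average of the 5 lines, and the difference of that response between lines.

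Markers matched the labels of SKMEL28, 94T778 (by its amplicon) and the breast lines, but no list shown here identified A375 or set SKBR3 apart from AU565. The melanocyte list had a median over its genes of 0.715 CPM in untreated A375 and 410 CPM in untreated SKMEL28. The premelanosome gene PMEL stood at 4147 and 3735 CPM in the untreated SKMEL28 libraries and at 1.17 to 22.1 CPM in the untreated libraries of the other lines. Genes of the chromosome 12q amplicon, which is amplified in well differentiated liposarcoma, summed to 12060 CPM in untreated 94T778. In the other untreated lines they summed to 269 CPM in SKBR3 up to 913 CPM in A375. The adipocyte list did not mark 94T778, with a sum of 89.9 CPM untreated against 608 CPM in untreated A375. The luminal and HER2 breast list summed to 29990 CPM in untreated SKBR3 and 23420 CPM in untreated AU565, against 352 CPM in untreated SKMEL28, 655 CPM in 94T778 and 904 CPM in A375. The untreated replicates of SKBR3 and of A375 differed from each other. In SKBR3, untreated replicate 1 had 7.63% of counts from mitochondrially encoded genes and replicate 2 had 4.44%, and the nuclear RNA MALAT1 stood at 1245 and 700 CPM. NEAT1, another nuclear RNA, rose with torkinib by 1.55 on the log2 scale in 94T778, 1.03 in A375, 0.73 in SKMEL28 and 1.695 in AU565 and had a change of 0.10 in SKBR3 (edgeR adjusted p = 0.656), and MALAT1 rose by 1.25 in 94T778, 1.30 in SKMEL28 and 0.36 in AU565. In A375, untreated replicate 1 carried genes of the 94T778 line at a median 4.47% of their untreated 94T778 level over 30 markers, against 0.771% in replicate 2. SKBR3 untreated replicate 2 held SKMEL28 markers at a median 0.3235% of their untreated SKMEL28 level with counts for 17 of 18, against 0.0434% and 11 markers in replicate 1 and 0% and 4 markers in each torkinib library, and PMEL stood at 22.06 and 6.853 CPM in replicates 2 and 1. MALAT1, NEAT1 and the markers of other lines were chosen after their values were seen.

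MTOR itself, the kinase that torkinib inhibits, fell by 0.28 on the log2 scale on the average of the lines (SE 0.04, edgeR adjusted p = 2.0e-08). Its level went from 295 ± 6.73 to 234 ± 14.0 CPM in SKMEL28 and from 120 ± 1.83 to 79.7 ± 2.93 CPM in AU565 (SD, n = 2 each), and it fell in SKBR3 as well. In A375 it stood at 123 ± 2.75 CPM untreated and 124 ± 8.92 CPM with torkinib (SD, n = 2 each). Among 18 genes of the MTOR complexes and their regulators, 4 rose and 9 fell. DEPTOR, an inhibitory subunit of both complexes, rose by 1.21 (SE 0.10) and in each of the 5 lines. RICTOR, the scaffold of the second complex, rose by 0.63 and TSC2, an inhibitor of the first, by 0.55. EIF4EBP1, the translation repressor phosphorylated by MTOR, fell by 0.99 on average and in 4 lines. The list mean was -0.06 (lower in 5 of 5 lines, exact permutation p = 0.0167), the list gave no call against other genes (camera adjusted p = 0.417), and the same 4 and 9 members were called when adjusted over the list alone.

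The list of homologous recombination, the repair of double-strand breaks from a sister copy, had a lower mean with torkinib in each of the 5 lines. Of 38 measured members, 25 fell and 7 rose on the average of the lines, the same numbers when adjusted over the list alone, and 19 fell and 2 rose in all 5 lines. RAD51AP1, which promotes strand exchange, fell by 2.85 on the log2 scale, RAD54L, a motor protein that moves along DNA, by 2.69, and the nuclease EXO1 by 2.76. BRCA1, which acts in the repair of breaks, fell by 1.75, with -0.65 in SKMEL28 and -3.09 in SKBR3, and the helicase BLM fell by 2.14. The mean log2 level of the list fell by 0.77, with values from -0.52 in SKMEL28 to -1.09 in SKBR3 (lower in 5 of 5 lines, exact permutation p = 0.000257, the smallest that 7776 relabellings within lines can give; 0.000595 after Benjamini-Hochberg adjustment over 37 scores). The list stood lower than other genes (camera adjusted p = 2.19e-06; adjusted p = 0.0255 with an estimated correlation). That call was lost with an estimated correlation in SKBR3 (adjusted p = 0.0859) and AU565 (adjusted p = 0.0964).

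The Fanconi anemia list, whose products repair cross-links between DNA strands, moved the same way. Of 23 members 17 fell and 5 rose, or 17 and 6 when adjusted over the list alone, and 8 fell in all 5 lines. FANCI and FANCD2, the pair that is ubiquitinated to start repair, fell by 2.10 (SE 0.05) and 1.84 (SE 0.06), with edgeR adjusted p of 3.6e-30 and 2.3e-25. UBE2T, the enzyme that conjugates that ubiquitin, fell by 2.50, and the core complex members FANCA and FANCG fell by 1.36 and 1.19. RFWD3, a ubiquitin ligase of the same pathway, fell by 0.70. The list mean fell by 0.69, from -0.52 in A375 to -0.89 in AU565 (lower in 5 of 5 lines, exact permutation p = 0.000257). Its camera adjusted p was 4.41e-04 and its adjusted p = 0.0229 with an estimated correlation, and in SKBR3 the call was lost with an estimated correlation (adjusted p = 0.0858).

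The replicative polymerases, the high-fidelity enzymes that copy the genome, had a lower list mean in all 5 lines, and the error-prone polymerases, which copy damaged templates or fill gaps, moved both ways. Of 10 replicative subunits 9 fell and none rose over all genes tested, while 9 fell and 1 rose when adjusted over the list alone. POLE2 fell by 2.31 (SE 0.11), POLA2 by 1.43, POLD3 by 1.03, POLD1 by 0.92, POLA1 by 0.84 and POLE by 0.83, each called in all 5 lines. POLD2 fell by 0.59, POLE4 by 0.57 and POLE3 by 0.43, and POLD4 had an average of 0.21 (edgeR adjusted p = 0.0813) with a rise of 1.01 in AU565. Among 10 error-prone members 5 rose and 3 fell, or 6 and 3 when adjusted over the list alone. POLQ, the polymerase of theta-mediated end joining, had the largest fall, by 3.53 (SE 0.11, edgeR adjusted p = 2.8e-25), and in SKBR3 it went from 11.9 ± 1.90 to 0.0798 ± 0.113 CPM (SD, n = 2 each), a ratio of 133 with a 95% counting interval of 23.5 to 5290 from 144 and 1 counts. MAD2L2, a subunit of polymerase zeta, fell by 1.04 in the average and in each line.

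POLI rose by 0.69 (SE 0.07) and in each of the 5 lines. REV3L, the catalytic subunit of polymerase zeta, rose by 0.51 on average and in 4 lines but fell by 0.46 in SKMEL28. POLL and POLM, gap-filling enzymes of end joining, rose by 0.47 and 0.30, and POLK by 0.17, a call that was lost when no filter on low counts was used (0.15, edgeR adjusted p = 0.0558). POLH, which copies past ultraviolet lesions, fell by 0.22 on average, with a rise of 0.42 in A375 and a fall of 1.04 in SKMEL28. REV1 had an average of 0.10 (edgeR adjusted p = 0.0626), and POLN had no counts in SKBR3, which leaves its average without a finite estimate. The replicative list mean fell by 0.86, with -0.64 in SKMEL28 and -0.95 in 94T778 (lower in 5 of 5 lines, exact permutation p = 0.000257; camera adjusted p = 1.12e-06; adjusted p = 0.00746 with an estimated correlation). The error-prone list mean was -0.09, at -0.12 in 94T778, 0.12 in A375, -0.14 in SKMEL28, -0.35 in SKBR3 and 0.05 in AU565 (exact permutation p = 0.0936). Its camera test pointed up although the mean was below 0 (adjusted p = 0.731). The replicative mean fell further than the error-prone mean, by 0.77 (lower in 5 of 5 lines, exact permutation p = 0.000257), and the error-prone mean without POLQ was 0.25 (exact permutation p = 0.000257). It was 0.017 with catalytic subunits only, POLQ among them (exact permutation p = 0.723), so the sign of the mean depended on which members were taken.

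**Figure D1:**
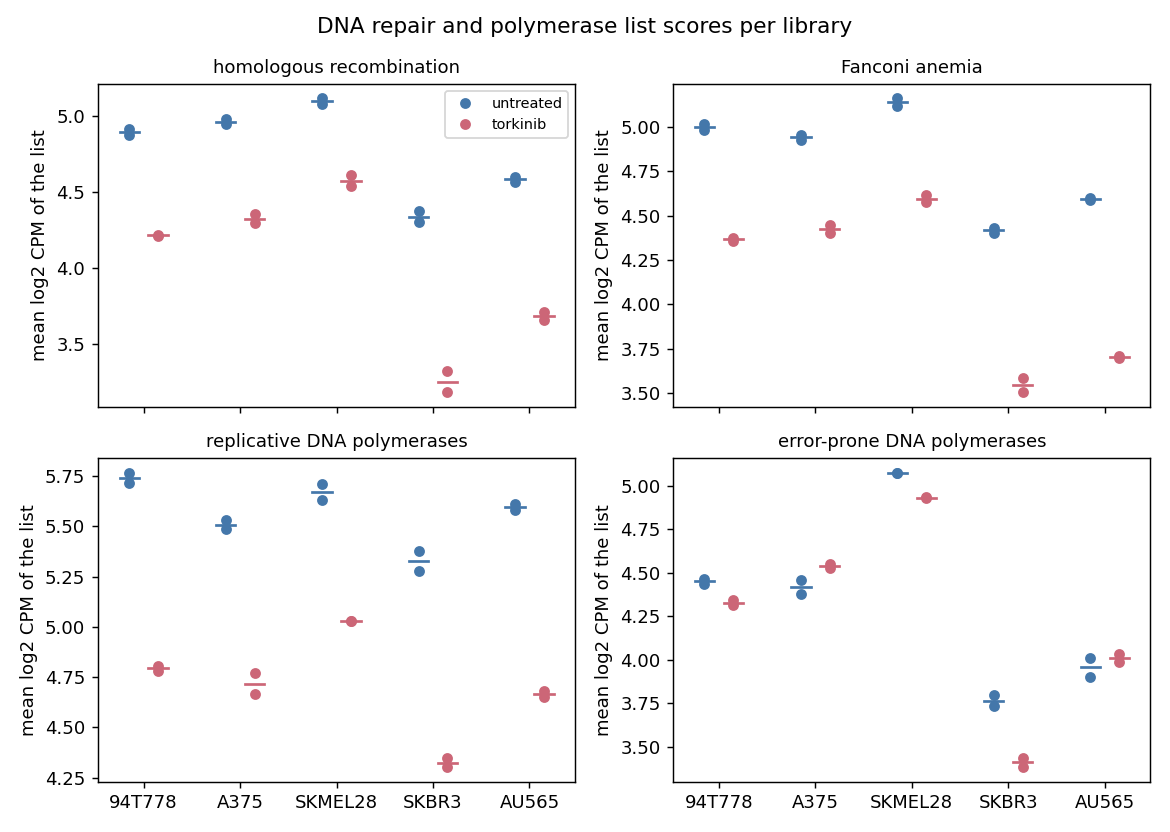
Mean log2 CPM of 4 gene lists (vertical axis) in each of the 20 libraries, grouped by cell line, with untreated and torkinib libraries as separate points and a bar at the mean of each pair. The torkinib pairs sit below the untreated pairs in all 5 lines for homologous recombination, Fanconi anemia and the replicative polymerases, and in 3 of 5 lines for the error-prone polymerases.

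Other repair lists held members that fell and members that rose. In base excision repair, which replaces single damaged bases, 14 of 22 members fell and 5 rose, the same when adjusted over the list alone, among them PARP2, which fell by 1.47, FEN1, the flap nuclease, by 1.38, PARP1 by 0.60 and the glycosylase NEIL3 by 3.24 (SE 0.14). The list was called lower (camera adjusted p = 2.38e-03; adjusted p = 0.0471 with an estimated correlation). It had no call in A375 (camera adjusted p = 0.0616) and SKMEL28 (camera adjusted p = 0.332) and lost it with an estimated correlation in 94T778 (adjusted p = 0.192), SKBR3 (adjusted p = 0.0859) and AU565 (adjusted p = 0.0993). Of 8 mismatch repair genes 4 fell and 3 rose, also when adjusted over the list alone; MSH6 fell by 0.42, and EXO1, which the list shares with homologous recombination, fell furthest. The list mean was -0.40, lower in 5 of 5 lines (exact permutation p = 0.000257), beside a median fitted change of -0.11 over the members, so EXO1 weighs on the mean, with no call against other genes (camera adjusted p = 0.262). Of 24 nucleotide excision repair genes 7 rose and 7 fell, with the same numbers adjusted over the list alone and a list mean of 0.01 beside a median fitted change of -0.03 (exact permutation p = 0.613, camera adjusted p = 0.855). The damage sensor XPC rose by 0.62 in the average and in each line, KIAA1530 rose by 0.76 and ERCC6, which acts at stalled transcription, by 0.60, while CCNH fell by 0.57. Of 11 end-joining genes 6 fell and 1 rose, the same adjusted over the list alone: the Ku subunits XRCC6 and XRCC5 fell by 0.41 and 0.35 and the kinase PRKDC by 0.28, and RIF1 rose by 0.28 (list mean -0.07, exact permutation p = 0.0355, which became 0.0505 when adjusted over the 37 scores; camera adjusted p = 0.258). In the DNA damage checkpoint list 10 of 16 members fell and 2 rose, also adjusted over the list alone, with TIMELESS at -1.71, CLSPN at -2.68 and the phosphatases CDC25A and CDC25C at -2.35 and -3.75. Its call (camera adjusted p = 1.55e-03) was lost with an estimated correlation (adjusted p = 0.201).

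Mitosis had the lowest mean of the 36 lists. All 27 measured mitosis genes fell on the average and in each of the 5 lines, and the list mean fell by 3.19, from -2.18 in A375 to -4.25 in SKBR3 (exact permutation p = 0.000257; camera adjusted p = 5.25e-33; adjusted p = 0.0229 with an estimated correlation). KIF20A, a kinesin of the midzone, fell by 3.91 (SE 0.06), the mitotic kinase PLK1 by 3.78 (SE 0.06), the topoisomerase TOP2A by 3.12 (SE 0.05) and the spindle factor TPX2 by 3.09 (SE 0.04). All 32 DNA replication genes fell on the average and 30 in all 5 lines, with a list mean of -1.71 (camera adjusted p = 2.14e-27; adjusted p = 0.0176 with an estimated correlation). Enzymes of nucleotide supply fell with them: RRM2 by 3.66, TK1 by 3.08 and TYMS by 2.26, and the origin licensing factor CDC6 fell by 2.75. Both lists gave the same counts when adjusted over the list alone. Among 21 regulators of the G1 phase 10 fell and 6 rose, or 10 and 7 adjusted over the list alone, with E2F2 at -3.08, E2F1 at -2.30, CDKN2C at -1.66 and CCND3 at -1.18. Their list mean was -0.38, lower in 5 of 5 lines (exact permutation p = 0.000257), with no call against other genes (camera adjusted p = 0.129).

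Lipid synthesis lists were lower in all 5 lines. Of 24 cholesterol synthesis genes 22 fell and none rose, 13 of them in all 5 lines, including ACAT2 by 2.73, INSIG1, a sterol sensor, by 2.55 and DHCR7 by 2.22. The list mean fell by 1.15, from -0.66 in A375 to -1.75 in AU565 (exact permutation p = 0.000257; camera adjusted p = 6.69e-14; adjusted p = 0.0255 with an estimated correlation). All 13 fatty acid synthesis genes fell on the average, with a list mean of -1.14 (camera adjusted p = 6.42e-09; adjusted p = 0.0305 with an estimated correlation). The desaturase SCD fell by 2.17 and reached -4.44 in 94T778, and ACLY fell by 0.78 in the average and in each line. FASN, the fatty acid synthase, and SREBF1, a transcription factor of lipid synthesis, fell by 0.87 and 1.16 on average but rose by 0.43 and 0.27 in SKMEL28. Both counts were the same adjusted over the list alone. With an estimated correlation the cholesterol call was lost in A375 (adjusted p = 0.117), SKMEL28 (adjusted p = 0.0842) and SKBR3 (adjusted p = 0.0880), and the fatty acid call in A375 (adjusted p = 0.0736), SKMEL28 (adjusted p = 0.339) and SKBR3 (adjusted p = 0.107).

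Of 23 genes of glycolysis and the hypoxia response 22 fell and none rose, also adjusted over the list alone, with a list mean of -0.88 (exact permutation p = 0.000257; camera adjusted p = 2.93e-12; adjusted p = 0.00746 with an estimated correlation). With an estimated correlation the call was lost in SKBR3 (adjusted p = 0.0880) and AU565 (adjusted p = 0.0600). PGAM1 fell by 1.63, TPI1 by 1.23 and ENO1 by 1.01 in the average and in each line. LDHA, the lactate dehydrogenase subunit, fell by 1.28 on average and by 3.24 in 94T778 but rose by 0.67 in A375. Of 40 nuclear genes of oxidative phosphorylation 37 fell and none rose, the same adjusted over the list alone, with a list mean of -0.55, from -0.14 in A375 to -1.03 in AU565 (camera adjusted p = 6.28e-18; adjusted p = 0.0176 with an estimated correlation). The list had no call in A375 (camera adjusted p = 0.234) and lost it with an estimated correlation in 94T778 (adjusted p = 0.144) and SKMEL28 (adjusted p = 0.382). UQCRC1 fell by 1.07, COX7B by 1.03, NDUFA9 by 0.91 and SDHB by 0.83. Of the 12 mitochondrially encoded genes 6 rose and 1 fell, the same adjusted over the list alone, and MT-ND1 rose by 0.72 and MT-ATP6 fell by 0.33 (camera adjusted p = 0.20). In SKMEL28 9 rose and none fell (camera adjusted p = 0.00679), a call lost with an estimated correlation (adjusted p = 0.528).

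Targets of the transcription factor ATF4, which drive amino acid supply, had a lower list mean in 4 lines, and no test compared these with AU565, where it was above 0. Of 22 members 18 fell and 3 rose on the average, also adjusted over the list alone, with a list mean of -0.99, at -2.21 in A375, -1.38 in SKMEL28, -0.77 in 94T778 and 0.40 in AU565 (exact permutation p = 0.00232; camera adjusted p = 2.26e-09; adjusted p = 0.00394 with an estimated correlation). DDIT4, an inhibitor of MTOR signalling, fell by 3.07 (SE 0.06), the serine synthesis enzymes PSAT1 and PHGDH fell by 1.98 and 1.77, and the mitochondrial folate enzyme MTHFD2 by 1.36. The unfolded protein response list had 12 of 16 members lower and 3 higher, the same adjusted over the list alone, with XBP1 at -1.07, HYOU1 at -0.89, CALR at -0.77 and PDIA4 at -0.73. Its call (camera adjusted p = 2.32e-05) was lost with an estimated correlation (adjusted p = 0.108).

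Genes for cytosolic ribosomal proteins, whose messages are translated under MTOR control, rose. Of 75 members 73 rose and none fell on the average, also adjusted over the list alone, and the list mean rose by 0.64, with 0.01 in 94T778, 0.52 in SKBR3, 0.63 in A375, 0.70 in AU565 and 1.33 in SKMEL28 (exact permutation p = 0.000772; camera adjusted p = 5.19e-38; adjusted p = 0.0229 with an estimated correlation). In 94T778 18 members rose and 21 fell. RPS27 rose by 1.24, RPL13 by 1.11, RPL23 by 1.02 and RPS13 by 0.94. With an estimated correlation the calls were lost in SKBR3 (adjusted p = 0.0869) and AU565 (adjusted p = 0.0600). The 27 ribosome biogenesis genes were mixed, with 12 lower and 8 higher, the same adjusted over the list alone: POLR3G fell by 1.54, LYAR by 0.63 and NOP2 by 0.44, and NOB1 rose by 0.40 (list mean -0.12, exact permutation p = 0.0460, which became 0.0631 when adjusted over the 37 scores; camera adjusted p = 0.272). In 94T778 17 fell and 3 rose and the list was called lower (camera adjusted p = 0.00154; adjusted p = 0.0128 with an estimated correlation), and in SKBR3 14 fell and 1 rose (camera adjusted p = 0.0238), a call lost with an estimated correlation (adjusted p = 0.0858). In SKMEL28 9 rose and 3 fell (camera adjusted p = 0.101).

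Of 19 targets of FOXO factors and receptor feedback genes 14 rose and 3 fell, also adjusted over the list alone, with a list mean of 0.63 (higher in 5 of 5 lines, exact permutation p = 0.000257). TXNIP, a brake on glucose uptake, rose by 1.89, FOXO1 by 1.38, the ubiquitin ligase FBXO32 by 1.18 and FOXO3 by 0.96. The call (camera adjusted p = 2.46e-05) was lost with an estimated correlation (adjusted p = 0.108). In the MAPK output list 10 of 16 members rose and 4 fell, or 10 and 5 adjusted over the list alone, with a list mean of 0.47 (exact permutation p = 0.00309; camera adjusted p = 5.07e-03; adjusted p = 0.0273 with an estimated correlation). By line, with no test of the list between lines, its mean was 1.279 in 94T778 (12 rose and none fell), 0.64 in SKMEL28, 0.39 in AU565, 0.06 in A375 (5 rose and 8 fell) and -0.03 in SKBR3 (6 and 6), and the calls in SKMEL28 and AU565 were lost with an estimated correlation (adjusted p = 0.0842 and adjusted p = 0.0873). Its immediate early genes FOS and EGR1 rose by 2.82 and 2.41, PHLDA1 by 0.75 and the phosphatase DUSP4 by 0.53. Autophagy genes went both ways, 12 higher and 9 lower of 27 with the same numbers adjusted over the list alone, and ATG14, the receptor SQSTM1, RB1CC1 and NBR1 rose by 1.08, 0.66, 0.67 and 0.60 (camera adjusted p = 0.258). In 94T778 15 rose and 3 fell and the list was called higher (camera adjusted p = 0.00318; adjusted p = 0.0175 with an estimated correlation), while in A375 5 rose and 11 fell (camera adjusted p = 0.661). Of 29 lysosomal genes 14 rose and 11 fell, or 15 and 11 adjusted over the list alone; TPP1 and ASAH1 rose by 0.81 and 0.74, and GLA and CTSZ fell by 1.20 and 0.80 (camera adjusted p = 0.394). Its calls as higher in A375 and SKMEL28 (camera adjusted p = 0.0169 and 0.0219) were lost with an estimated correlation (adjusted p = 0.324 and adjusted p = 0.382).

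In A375 all 12 measured members of the replication-dependent histone list rose, also adjusted over the list alone, and the list mean rose by 3.15 (camera adjusted p = 6.72e-11; adjusted p = 0.0102 with an estimated correlation). Over the 5 lines 6 of 12 rose and 1 fell, the same adjusted over the list alone, among them HIST1H4H by 2.79, HIST1H2BD by 2.69, HIST2H2BE by 1.93 and HIST1H2BK by 1.19. The average call (camera adjusted p = 7.75e-03) was lost with an estimated correlation (adjusted p = 0.0644). Histone genes have near-identical copies, which makes single values uncertain. The list was fixed beforehand as a sign of RNA quality, and its mean in untreated A375 stood at -0.17 log2 CPM. Whether its rise reflects RNA quality or expression was not tested.

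**Figure D2:**
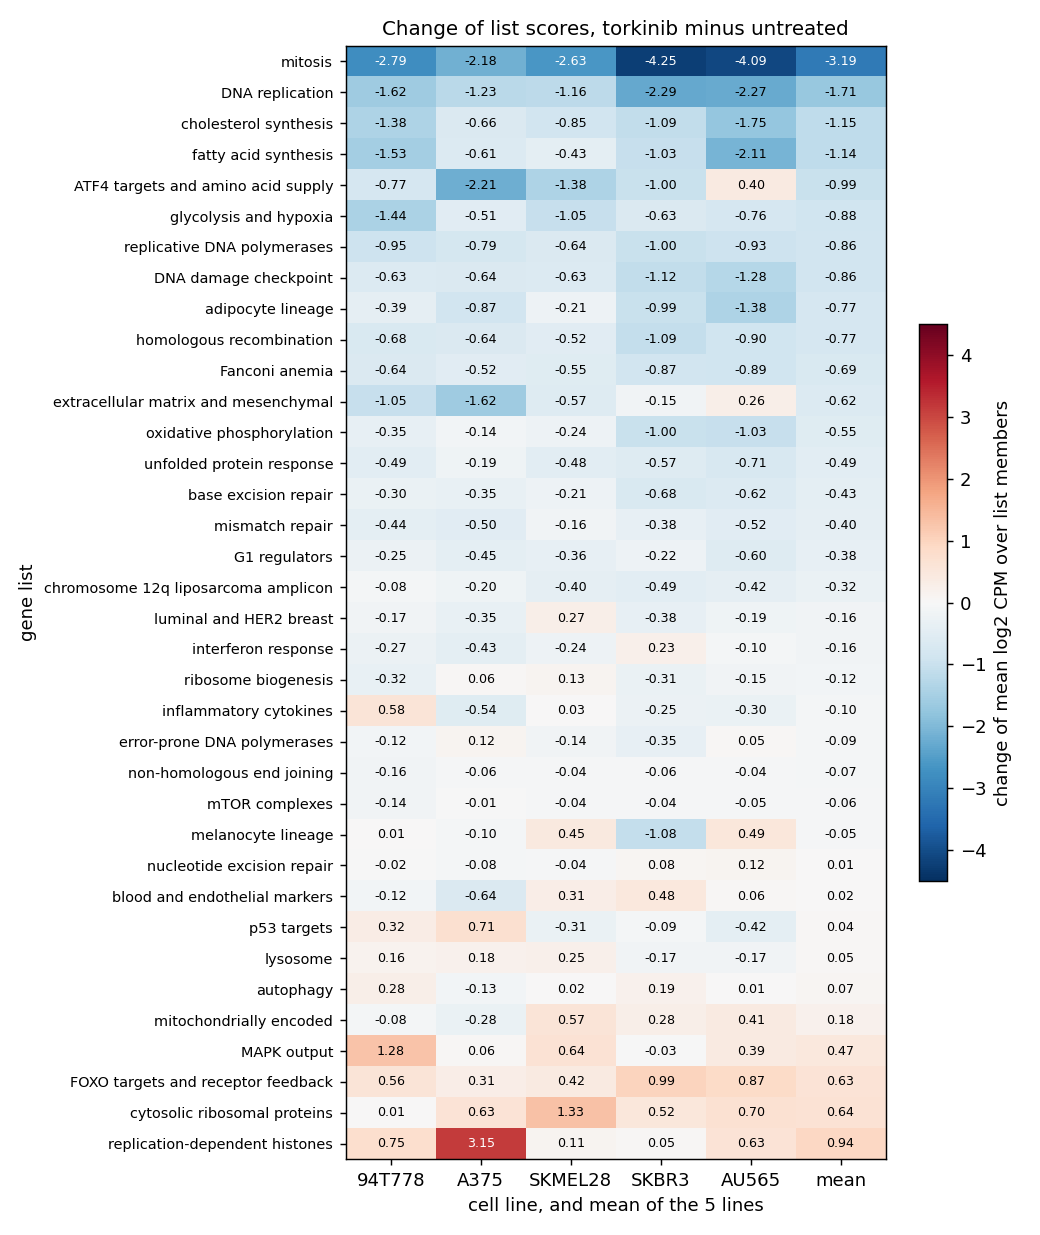
Change of the mean log2 CPM of each gene list, torkinib minus untreated, for the 5 lines and their mean (columns) and the lists (rows of the map); colour gives the log2 difference. Mitosis shows the lowest mean, -3.19, and the replication-dependent histones the highest single value, 3.15 in A375.

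Over all genes tested, 4734 rose and 4692 fell on the average of the lines, and 378 rose and 771 fell in all 5 lines, against 9.91 and 17.4 if the lines' calls were independent. SKBR3 and AU565 come from the same donor and are not independent, so these expected counts are a low bar. The balance of rises and falls depended on scaling: with upper-quartile factors 5490 rose and 4051 fell on the average, and 534 and 626 in all 5 lines. Among genes called in all 5 lines with counts in each group, the largest falls were those of MYBL2, a transcription factor of dividing cells, by 3.99 (SE 0.06), BIRC5, or survivin, by 3.76, DLGAP5 by 3.71, KIF14 by 3.65 and KIF4A by 3.63, together with KIF20A, PLK1, CDC25C and RRM2 given above. APLP1, a relative of the amyloid precursor, was also called lower in all 5 lines but had no torkinib counts in SKBR3, which leaves its average without a finite estimate. The largest rises were those of the amylase gene AMY2B by 3.44 (SE 0.17, edgeR adjusted p = 6.9e-20), TAS2R5 by 3.28 (SE 0.37), HIST1H2AC by 3.12 (SE 0.08), KLHDC1 by 2.90, C9orf69 by 2.87, KIAA1875 by 2.30, GTF2IRD2 by 2.23, C5orf41 by 2.18, the protease ADAMTS13 by 1.998 and MXRA8 by 1.86. AMY2B, GTF2IRD2 and HIST1H2AC have close copies elsewhere in the genome, and TAS2R5, a taste receptor gene with few counts, had 1 or 2 untreated counts in 4 lines.

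In 94T778, 3968 genes rose and 3970 fell, and 4826 and 3247 with library totals as scaling. SLC16A6, a transporter of the monocarboxylate family, rose from 3.82 ± 0.403 to 294 ± 37.7 CPM, a log2 change of 6.26 (SE 0.23), and the cytokine IL24 from 11.8 ± 1.69 to 285 ± 69.8 CPM (SD, n = 2 each). IQCD rose by 5.17, FOS by 4.33, the sodium-proton exchanger SLC9A3 by 4.12 and AMY2B by 3.82. CYP24A1, the enzyme that inactivates vitamin D, fell by 5.09 (SE 0.11), from 814 ± 37.3 to 23.8 ± 2.28 CPM (SD, n = 2 each). LRRC17 fell by 5.72, the kinase ALPK2 by 5.63, SERPINB7 by 5.30 and ID3, an inhibitor of helix-loop-helix factors, by 4.97. The cation channel TRPM2 fell from 8.89 ± 1.46 to 0.0630 ± 0.0891 CPM (SD, n = 2 each), a ratio of 131 with a 95% counting interval of 23.0 to 5217 from 105 and 1 counts. Of 19 extracellular matrix and mesenchymal genes 12 fell and 5 rose in this line, or 13 and 5 adjusted over the list alone (camera adjusted p = 4.07e-04); the call was lost with an estimated correlation (adjusted p = 0.0630).

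In A375, 3089 genes rose and 4051 fell, so that 43.3% of calls were higher, and 53.4% were higher with upper-quartile scaling. Histone genes were among the strongest rises: HIST2H2BE from 2.69 ± 0.253 to 87.5 ± 0.967 CPM, HIST1H2BD by 4.79, HIST2H2AA3 by 5.72 and HIST1H4E by 4.92, and HIST1H4H at a ratio of 74.4 with a 95% counting interval of 20.1 to 623. FOS rose from 8.65 ± 1.94 to 320 ± 43.0 CPM (SD, n = 2 each). KRT81, a hair keratin, fell from 76.2 ± 5.96 to 0.334 ± 0.174 CPM (SD, n = 2 each), and NUPR1, a stress-induced nuclear protein, fell by a ratio of 141 with a 95% counting interval of 24.9 to 5575. The activin subunit INHBE had no counts with torkinib and was at least 46.1-fold lower. The transcription factor gene PAX8 and the junction gene CLDN11 also had no torkinib counts, and no bound is given for them, since their untreated level rested on 1 library. Untreated replicates 1 and 2 stood at 21.9 and 1.87 CPM for PAX8, 22.8 and 0.936 CPM for CLDN11 and 81.2 and 20.9 CPM for the collagen COL6A3, which fell by 6.92, with the higher value in the library that carried 94T778 genes. Of 19 extracellular matrix genes 14 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 8.72e-06; adjusted p = 0.0341 with an estimated correlation), and FN1, at 709 and 66.2 CPM in the same untreated replicates, fell by 4.20. The matrix list scored 5.40 and 4.78 log2 CPM in untreated replicates 1 and 2, and 3.49 and 3.46 with torkinib. Its call was not recomputed without the library that carried 94T778 genes. Without the genes for which 94T778 reads could make up a large part, 3128 genes rose and 3977 fell.

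In SKMEL28, 3402 genes rose and 3953 fell, and with upper-quartile scaling the balance turned to 4078 and 3348. The largest rises included EGR1, an immediate early transcription factor, from 16.8 ± 0.286 to 549 ± 26.2 CPM, FOS from 13.0 ± 1.31 to 288 ± 13.0 CPM and FOSB from 2.17 ± 0.307 to 77.1 ± 6.91 CPM (SD, n = 2 each). NR4A2, a nuclear receptor, rose by 3.52, C19orf20 by 3.70 and the olfactory receptor gene OR2C3 by 3.56. The lysyl oxidase LOXL2 fell by 4.71 (SE 0.16) and the protease ADAM19 by 4.34 (SE 0.17), from 53.7 ± 7.36 to 2.05 ± 0.0304 and from 50.1 ± 3.66 to 2.45 ± 0.398 CPM (SD, n = 2 each). SERPINA3 fell by 4.61, RRM2 by 4.22 and DDIT4 by 3.81. FLT1, a receptor for vascular endothelial growth factor, fell by a ratio of 45.4 with a 95% counting interval of 15.1 to 224. Of the 16 MAPK output genes 6 rose and 4 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.0239); the call was lost with an estimated correlation (adjusted p = 0.0842).

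In SKBR3, 4109 genes rose and 4460 fell. NT5E, a cell-surface nucleotidase, rose from 21.6 ± 8.44 to 689 ± 57.0 CPM and CYP1A1, a target of the aryl hydrocarbon receptor, from 12.6 ± 2.96 to 348 ± 2.53 CPM (SD, n = 2 each). The protease inhibitor TFPI2 rose by 5.31, ARHGAP28 by 4.80 and EFNB2, an ephrin ligand, by 4.71. CRAT, the carnitine acetyltransferase, fell by 6.76 (SE 0.21), from 98.0 ± 2.68 to 0.896 ± 0.139 CPM (SD, n = 2 each). APLP1, the acute phase gene ORM1, C10orf27 and the sulfotransferase SULT2B1 had no counts with torkinib and were at least 48.6-fold, 48.0-fold, 44.0-fold and 40.03-fold lower. The C10orf27 call was lost with DESeq2 (adjusted p = 0.317). The higher mitochondrial share and MALAT1 level of untreated replicate 1 bear on each SKBR3 value, and without this library and A375 untreated replicate 1, 3707 genes rose and 4379 fell. Without untreated replicate 2, which held the SKMEL28 markers, 3912 rose and 4103 fell.

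In AU565, 4497 genes rose and 4779 fell, and with upper-quartile scaling the balance turned to 5253 and 4143. CYP1A1 rose from 38.3 ± 2.79 to 1431 ± 18.4 CPM, a log2 change of 5.22 (SE 0.09), and LBH, a developmental cofactor, from 1.60 ± 0.456 to 58.4 ± 1.60 CPM (SD, n = 2 each). TFPI2 rose by 4.68, AMY2B by 4.67, VWA2 by 4.66, and the protease CAPN3 by a ratio of 52.7 with a 95% counting interval of 17.6 to 259. The fibrinogen chain gene FGB had 65.4 ± 2.43 CPM untreated and no counts with torkinib, at least 261-fold lower, and FGG fell from 106 ± 0.507 to 0.168 ± 0.0309 CPM (SD, n = 2 each), a ratio of 635 with a 95% counting interval of 176 to 5246. AKR1C2, a steroid-metabolising reductase with close relatives, was at least 187-fold lower, and GPR141 at least 43.6-fold lower, a call lost with DESeq2 (adjusted p = 0.300). RBP4, the carrier of retinol, and CLCA2 fell by ratios of 255 and 253, each from 1 torkinib count, with lower 95% counting bounds of 45.4 and 45.2.

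The response differed between lines in 11417 genes by a joint test of the 5 lines, and 4000 genes were called in opposite directions in at least 2 lines. Across genes, the log2 changes of SKBR3 and AU565 correlated at r = 0.576 (rho 0.619), and those of the other pairs of lines at 0.17 to 0.32; genes are not independent replicates. IGFBP3, which binds insulin-like growth factors, rose by 2.86 in SKBR3, 3.06 in AU565 and 1.04 in A375 and fell by 2.29 in 94T778 and 3.53 in SKMEL28. ASNS, asparagine synthetase, rose by 1.38 in AU565 and fell in the other 4 lines, and CBS, of cysteine synthesis, rose by 3.35 in AU565 and fell by 3.50 in A375. The aldehyde dehydrogenase ALDH1A3 rose by 2.16 in SKBR3 and fell by 1.92 in SKMEL28. FOS rose by 5.22 in A375 and fell by 0.48 in SKBR3, where it already stood at 1150 CPM untreated. CRAT fell by 6.76 in SKBR3 and 3.73 in AU565 and rose by 0.53 in both 94T778 and SKMEL28. NT5E rose in 4 lines and fell by 0.41 in A375, LDHA fell in 4 lines and rose in A375, and GPR110, an adhesion receptor with no counts in SKMEL28, rose by 3.82 in SKBR3 and fell by 3.59 in A375.

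Between the melanoma lines, treated at the same dose, 2231 genes responded more positively in A375 and 2514 more negatively than in SKMEL28. FLT1 rose from 8.75 to 39.6 CPM in A375 and fell in SKMEL28, and KRT81 fell in A375 and stood at 0.766 and 0.789 CPM in SKMEL28. UNC13D, a factor of granule release, fell from 8.97 to 0.621 CPM in A375, and ADAMTSL1 from 8.47 to 0.182 CPM; both had no counts in untreated SKMEL28. The receptor gene LPHN3 rose from 2.92 to 16.5 CPM in A375. PCSK2, a prohormone convertase, fell from 69.9 to 35.8 CPM in SKMEL28. In A375 PCSK2 had no untreated counts and 14 with torkinib, at least 6.88-fold higher. CD96 stood at 182 and 210 CPM in A375 (edgeR adjusted p = 0.0846) and at 1.29 and 0 CPM in SKMEL28. The differences of CD96 and LPHN3 lost their calls without SKMEL28 untreated replicate 2 (3.74, edgeR adjusted p = 0.229, and 2.47, adjusted p = 1.00), and those of INHBE and ADAMTSL1 without SKMEL28 torkinib replicate 2 (-7.38, adjusted p = 0.0746, and -5.44, adjusted p = 1.00).

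Between the breast lines, treated at doses of 0.8 and 4 µM, 2179 genes responded more positively in SKBR3 and 1801 more negatively than in AU565, and of the genes called in both, 93.6% moved in the same direction. SELE, an adhesion molecule of activated endothelium, fell from 11.3 to 0.432 CPM in AU565 and stood at 0.532 and 1.27 CPM in SKBR3, and the transporter ABCG2 rose from 0.459 to 3.12 CPM in SKBR3 and fell from 28.4 to 12.3 CPM in AU565. The hormone subunit CGA fell from 11.5 to 0.995 CPM in SKBR3, the receptor TGFBR3 rose from 12.6 to 25.4 CPM in AU565 and fell in SKBR3, and the zinc finger gene ZNF175 rose from 0.0686 to 3.10 CPM in AU565. FOXN4, a forkhead factor, fell from 8.43 to 0.220 CPM in AU565, SULT2B1 from 6.95 to 0.578 CPM and PON3 from 8.90 to 2.45 CPM. SULT2B1 and PON3 fell further in SKBR3, from 130 and 26 untreated counts to no torkinib counts. They were at least 40.03-fold and 8.0-fold lower there. The filamin-binding gene FBLIM1 rose from 5.05 to 9.01 CPM in SKBR3. Of the differences given here 4 lost their calls when 1 library was left out, and the fitted difference that remained is given in brackets. FBLIM1 lost its call without AU565 untreated replicate 1 (3.59) or torkinib replicate 1 (3.52). SULT2B1 lost it without torkinib replicate 2 of SKBR3 (-5.64) or AU565 (-5.60), and PON3 without SKBR3 torkinib replicate 1 (-5.01) or 2 (-5.00) or AU565 torkinib replicate 1 (-4.78). FOXN4 lost it without SKBR3 untreated replicate 2 (4.94), either untreated AU565 library (6.01 and 5.90), SKBR3 torkinib replicate 2 (2.53) or AU565 torkinib replicate 1 (5.17).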

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

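The tests on 94T778 marker genes in A375 were chosen only after the result was seen; the counts of other splits were planned before.

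The torkinib response differed between lines in 11417 of 16698 genes by a joint test of the 5 lines, in 4745 genes between A375 and SKMEL28 and in 3980 between SKBR3 and AU565. Among genes called in opposite directions, edgeR's adjusted p of the difference between lines was 2.39e-28 for IGFBP3, 4.47e-26 for ASNS, 1.71e-25 for ALDH1A3, 2.91e-25 for FOS and 8.38e-25 for CRAT. It was 1.65e-24 for CBS and 1.79e-24 for each of NT5E, LDHA and GPR110. IGFBP3, ASNS, ALDH1A3 and CBS rose in AU565 and fell in SKMEL28, by 3.53, 3.37, 1.92 and 3.12 on the log2 scale.

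Between A375 and SKMEL28 the log2 change differed, A375 minus SKMEL28, by 9.45 for HIST2H2AA3, 7.51 for FLT1, 7.06 for PCSK2, 6.63 for CD96 and 6.58 for LPHN3. The difference was -10.56 for PAX8, -8.72 for INHBE, -8.60 for UNC13D, -8.38 for ADAMTSL1 and -7.91 for KRT81; the untreated PAX8 level in A375 rested on the library with 94T778 genes. Between SKBR3 and AU565, SKBR3 minus AU565, it was 5.95 for FOXN4, 5.80 for SELE, 4.23 for FBLIM1 and 3.84 for ABCG2. In the other direction it was -5.63 for SULT2B1, -5.07 for TGFBR3, -4.99 for PON3, -4.95 for CGA and -4.90 for ZNF175. Of the 20 genes the rule took from the 2 pairs, 11 had no counts in at least 1 of the 4 groups compared and 5 more had 1 to 3 counts in one, so their fitted differences depend on the prior count and are no bounds.

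The error-prone polymerase list differed between the melanoma lines, with a mean fitted change of 0.31 in A375 and -0.13 in SKMEL28, a difference of 0.44 (fry adjusted p = 0.0017 over the 40 tests of 4 lists in all pairs of lines). Camera did not set the list apart from other genes in this difference. Of those 40 tests 23 passed by fry and none by camera, so this list was not alone. All 4 lists passed between SKMEL28 and AU565, treated at the same dose. The fry adjusted p was 0.0109 for homologous recombination, 9.28e-04 for Fanconi anemia, 0.00680 for the replicative and 0.00229 for the error-prone polymerases. Between A375 and AU565, also at that dose, only Fanconi anemia passed (fry adjusted p = 9.28e-04). Between A375 and SKMEL28 only the error-prone list passed. POLN rose in A375 by a ratio of 20.6 from 1 untreated count (95% counting interval 3.14 to 872), which weighs on the mean, and POLH, REV3L and REV1 stood at 0.42, 0.51 and 0.32 in A375 against -1.04, -0.46 and -0.13 in SKMEL28.

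Outside the counted reads, the share that aligned at more than 1 place was higher with torkinib by 2.005 percentage points on the mean of the lines (higher in 5 of 5 lines, exact permutation p = 0.000257).

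Genes of the 94T778 line appeared in A375 untreated replicate 1. Over 30 genes with at least 50 CPM in 94T778 and under 1 CPM in the 3 lines other than A375, the median share of the 94T778 level was 4.47% in replicate 1 and 0.771% in replicate 2, which argues against expression by untreated A375 cells, and the ratio was 5.79 with 90% of markers higher in replicate 1. The excess of the 7 amplicon genes was 0.361 of the median marker share, but that share also holds what A375 itself expresses, and against the excess of replicate 1 over replicate 2, a median of 1.69%, the ratio was 0.954. These values are consistent with RNA or reads of 94T778 in that library, with MDM2 at 249 and 119 CPM and FN1 at 709 and 66.2 CPM in the 2 replicates (MDM2 was chosen after its values were seen); whether cells, RNA or reads were mixed stays open. Of 163 genes exposed to it 41 were called lower in A375 and none higher. Of all 16698 genes tested 4051 were called lower and 3089 higher in A375. The exposed genes were chosen by their level in that library, so all genes tested are no fair base for their share of falls. These counts do not decide whether 94T778 reads added falls.

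Whether other groupings of the libraries give as many genes was tested on 100 splits of the libraries within lines, the real one included. With the real split, 4734 genes rose and 4692 fell on the average, and the highest of the other splits gave 3526 in either direction, so 1 of 100 splits reached either count. In all 5 lines 378 rose and 771 fell, the highest other split gave 12, and again 1 of 100 reached each count. The other splits mixed torkinib and untreated libraries, which widens the spread within groups where genes respond, so the real split was favoured. These counts bear only on the labels of these libraries, and chance between cultures was not tested.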

How the results depend on the processing

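Of 571 recomputed values of the counts and list changes 549 were kept: a count when it stayed within 1.5 times, a list change when it held its direction and side of the threshold. The genes or libraries in doubt, and genes with no count in some group, were left out only after the data were seen. With a fold threshold of 1.5, which is stricter by construction, 1275 genes rose and 1418 fell in 94T778, 717 and 1636 in A375, 1076 and 1311 in SKMEL28, 1620 and 2213 in SKBR3 and 2138 and 2282 in AU565; 1011 and 1266 on the average; 24 and 225 in all 5 lines. It left 1388 differences between A375 and SKMEL28 and 701 between SKBR3 and AU565, and the joint test of lines has no such threshold. The error-prone list was called lower with a prior count of 5 (-0.094, exact permutation p = 0.0165) and without A375 (-0.14, p = 0.0139, by exact permutation). It stood at 0.017 with catalytic subunits only (exact permutation p = 0.723) and at 0.25 without POLQ (exact permutation p = 0.000257), so its sign depended on the members taken; elsewhere the cause was not tested. Leaving out each library in turn gave -0.101 to -0.080, called only without AU565 untreated replicate 2 (exact permutation p = 0.0468). A group left with 1 library was assumed to vary like the others.

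Fry called 30 lists against 17 by camera, since it does not compare lists with other genes. Leaving out libraries in turn kept the average between 4517 and 4820 higher and 4535 and 4845 lower, and homologous recombination between -0.79 and -0.76. Without A375 and SKBR3 untreated replicate 1, 4756 rose and 4752 fell on the average, and 396 and 795 in all 5 lines; with genes lacking counts in some group left out, 4696 and 4501, 416 and 752, and 10259 differed between lines. Upper-quartile factors moved the median change in AU565 by 0.115 and library totals that in 94T778 by 0.108. Of the values of single named genes 8900 kept their call, 43 lost it, 66 gained it and 8 changed sign without a call on the average: GPR110 to 0.0031, FOXN4 to 0.24, 0.22 and 0.24, LBH to 0.32 and 0.49, FBLIM1 to 0.084 and ABCG2 to 0.031. GPR110, FOXN4 and LBH had a group with no counts, so their averages have no finite estimate. The cause was not tested. Leaving out each library in turn gave these averages from -0.61 for LBH, -1.03 for FOXN4, -1.49 for FBLIM1 and -0.42 for ABCG2. Replicate numbers were not shown to pair libraries in 94T778, A375, SKMEL28 and AU565. Their correlations of same-number deviations were below 0, down to -0.0863 at mean log2 CPM above 3. In SKBR3 the correlation was 0.219, and 0.288 at mean log2 CPM above 4, so its numbers may pair libraries. With the replicate block, the average gave 4739 and 4721 and all 5 lines 388 and 775, 11362 differed between lines, and the error-prone list had p = 0.164 by exact permutation and stayed uncalled.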

Other observations

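The tests of repair lists against the replication list and against mitosis were chosen only after the result was seen; those on shared members and on ribosomal protein genes were planned before their results were seen.

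Lineage and immune genes moved in both directions. In the interferon list 8 of 22 genes rose and 6 fell, the same adjusted over the list alone: OAS3, which senses double-stranded RNA, fell by 1.01, OAS1 by 1.06 and IFI6 by 1.16, the last reaching -3.43 in SKBR3 with a rise of 0.87 in SKMEL28, and TAP1, a peptide transporter, rose by 0.50. The list mean was -0.16 (exact permutation p = 0.0329), at 0.23 in SKBR3 and below 0 in the other 4 lines, while its camera test pointed up (adjusted p = 0.861). Among 15 inflammatory genes 3 fell and 2 rose, also adjusted over the list alone; the cytokine LIF fell by 1.47 and ICAM1 by 0.24, and the NF-kappa-B inhibitors TNFAIP3 and NFKBIA rose by 0.96 and 0.35 (camera adjusted p = 0.968). In 94T778 10 rose and 3 fell (camera adjusted p = 0.0281), a call lost with an estimated correlation (adjusted p = 0.429). Of 15 p53 targets 5 rose and 3 fell, also adjusted over the list alone, with BBC3, which promotes apoptosis, up by 1.39 in the average and called in each line, TP53INP1 up by 0.99, RRM2B up by 0.51 and C12orf5 down, at -1.23. The list mean was 0.04 with a mean fitted change of -0.06 (camera adjusted p = 0.855). The list was not tested between lines. In A375 12 rose and 1 fell with a list mean of 0.71 (camera adjusted p = 1.32e-06; adjusted p = 0.0149 with an estimated correlation). In 94T778 9 rose and 3 fell (camera adjusted p = 0.0664), in SKMEL28 2 and 9 (adjusted p = 0.197), in SKBR3 4 and 7 (adjusted p = 0.849) and in AU565 2 and 7 (adjusted p = 0.380). Of 19 extracellular matrix genes 9 fell and 2 rose over the lines, the same adjusted over the list alone: FN1 fell by 1.70 and THBS1 by 1.13 (list mean -0.62, exact permutation p = 0.00720, with 0.26 in AU565; camera adjusted p = 0.223). FN1 is among the genes exposed to 94T778 reads in A375 untreated replicate 1, and the list was not retested without that library. COL1A1, also called lower, had no torkinib counts in A375, which leaves its average without a finite estimate.

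Of 13 melanocyte genes 1 rose and 1 fell, also adjusted over the list alone. The lineage factor MITF rose by 0.77 in SKMEL28, where PMEL rose by 0.80 and RAB27A and SOX10 by 0.28 and 0.39, and MITF fell by 0.74 in A375 (on the average the list mean was -0.05 and the camera test pointed up, adjusted p = 0.924). In SKMEL28 10 rose and 2 fell (camera adjusted p = 6.97e-04), a call lost with an estimated correlation (adjusted p = 0.255). In SKBR3 the list mean was -1.08, beside the SKMEL28 markers in its untreated replicate 2. Of 19 luminal and HER2 genes 4 fell and 1 rose, or 4 and 0 adjusted over the list alone, and ERBB2, the HER2 receptor, fell by 0.72 in SKBR3 and 0.74 in AU565, while XBP1 fell by 2.02 and 1.71 and KRT18 by 0.40 in SKBR3 (camera adjusted p = 0.384 on the average). Of 9 adipocyte genes 4 fell and none rose, also adjusted over the list alone: PPARG, the adipogenic nuclear receptor, fell by 1.54 in the average and in each line, LIPE by 1.23 and PLIN2, a lipid droplet protein, by 0.87 with a rise of 0.41 in 94T778, and CD36, also called lower, had no torkinib counts in SKBR3. The list mean was -0.77, lower in 5 of 5 lines (exact permutation p = 0.000772), with no call against other genes (camera adjusted p = 0.198), and the calls in A375 and AU565 (camera adjusted p = 0.0369 and 0.0284) were lost with an estimated correlation (adjusted p = 0.324 and adjusted p = 0.359). Among 7 genes of the 12q amplicon 2 rose and 2 fell, the same adjusted over the list alone, with CPM, a carboxypeptidase, at -2.31, TSPAN31 at 0.62, FRS2 at 0.21 and YEATS4 at -0.21. Their list mean was -0.32, lower in 5 of 5 lines (exact permutation p = 0.00129), with no call against other genes (camera adjusted p = 0.855). None of 5 blood and endothelial genes was called on the average by edgeR's test, also adjusted over the list alone. At an unadjusted p under 0.05 it gave 1, the macrophage marker CD68 at -0.12, and DESeq2 and limma-voom called neither CD68 nor VWF. The list mean was 0.02 while its camera test pointed down (adjusted p = 0.855).

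The list means of homologous recombination and Fanconi anemia were lower in all 5 lines, with 19 of 38 and 8 of 23 members called lower in each line, and a candidate explanation is that fewer cells were in the cycle at 72 h. The mitosis list, whose products do not repair DNA, fell further than homologous recombination in each of the 5 lines, with the smallest gap at -1.54. Per the labels, doses were set to stop the cell cycle, so mitosis genes would fall whatever lowered the repair lists. Their fall therefore does not decide why the repair lists fell. The recombination score rose against the DNA replication score by 0.95 (exact permutation p = 0.000257), so as a whole the list did not fall beyond the replication list. That gap depends on list make-up, since 30 of 32 replication genes but 19 of 38 recombination genes were called lower in each line. It does not tell whether single recombination genes fell beyond replication genes. Leaving out EXO1, the 1 member in another list, gave -0.71 for the other 37, but 1 of 38 genes could not turn the mean, so this test decides nothing. A direct effect of MTOR inhibition on repair genes within cycling cells was not tested, since the libraries hold mixed cells.

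On the average of the lines, messages for cytosolic ribosomal proteins rose while MTOR, which drives their translation, was inhibited. Of the 75 members 18 rose in all 5 lines, and in 94T778 the list mean changed by only 0.01. Scaling was tested with 3 other sets of factors, and the list change was at least 0.64 in each (highest exact permutation p = 0.00103). These factors are all relative to the counts of each library, so none could show a change per cell. The larger library had the higher score in 4 of 10 groups, which argues against library size. Members with a pseudogene named after them that had counts (49) rose by 0.10 less than the 26 without, a difference of -0.10. Pseudogenes under other names were not looked for, so members among the 26 can have them. Reads aligned at more than 1 place stood outside the counts, and their share rose with torkinib by 2.005 percentage points. An effect of reads shared with pseudogenes therefore stays open. What raised the messages relative to other counts stays open: synthesis and stability were not measured, and RNA composition was not tested. The nuclear RNA NEAT1 rose in 94T778, where the list mean changed by 0.01, and was not called in SKBR3, where the list mean rose by 0.52. In the other lines both NEAT1 and the list mean rose.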
